A study of Mus musculus with 7 samples.

How the data were processed

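RNA was measured in the soleus, a predominantly slow hindlimb muscle, of 7 mice lacking tenascin-C, an extracellular matrix glycoprotein encoded by Tnc. Per the labels, the animals were cage controls, and the series title and design text give the strain as 129/SV and the samples as biological replicates. All 7 samples fall into 1 group, and no wild-type or treated sample was analysed here. The replicates are numbered in accession order and the numbers only name the samples. Replicate 1 carries the code C16 in its title and the other 6 carry C15, and the labels do not say what the code means.

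Per the labels' protocols, total RNA was extracted from cryosections of the muscle belly with a column kit. Then 4 µg of it was reverse transcribed with gene-specific primers in the presence of a radioactive nucleotide, and the labelled cDNA was hybridised to a 1-channel array. The array support, scanner, background treatment and software are not given in the sources used here. The deposited values are linear spot intensities for 223 probes on 7 arrays, with no missing value and none at or below 0. The file itself shows how the authors' intensity values were scaled. Without the probe for 28S rRNA and 1 unnamed probe, each array sums to between 0.998 and 1.00, so each value is a share of the array's summed signal. Signals are given here as percent of that sum, and the 2 probes outside the sum can exceed it. Values are recorded in steps of 0.01%, except 1 value with 6 decimals, Car3 in replicate 6. Because shares of a fixed sum constrain each other, a few bright probes can move the share of all the others. The amount of cDNA on a spot also depends on its primer and probe, so signals of different probes do not compare transcript numbers.

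Probes were named through the platform annotation supplied with the series. Of the 223 probes, 205 had 1 gene symbol, 18 had none and none had several. The Entrez identifiers of 204 named probes were found in a RefSeq table of mouse genes, and no symbol needed updating. Igf1 and Fn1 have 2 probes each and these were kept separate. No genome build is named by the files, so no coordinates are given.

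The file holds no detection flag. The 10th percentile of each array was taken as its floor, and a probe above 3 times the floor was called clearly above it. This criterion was chosen after seeing the data. Log2 of the deposited values was analysed without further scaling, since the plan, fixed before the data were examined, called for centring only if the values were not normalized. Spread between mice was tested per probe with limma, using an intercept-only design. Each probe's variance over 7 arrays (6 residual degrees of freedom) was compared with the robust variance trend over mean level in a one-sided F test. Benjamini-Hochberg adjustment covered all probes, at a threshold of 0.05. An adjustment over each list alone was outside the plan. The test was tested on simulated data, with 50 sets of 223 probes drawn from the fitted trend and 20 probes per set made more variable. For all 7 arrays it recovered 0.60% of probes with a 2-fold larger SD and 4.2% of those with a 4-fold larger SD. Without replicate 3 it recovered 1.2% and 16.8%. It thus recovers few of the more variable probes. The simulated noise was independent for each probe, so an array that deviates on many probes at once was not covered. Of the calls of the test, 7.69% and 1.10% were false. These shares rest on means of 0.04 and 0.02 false calls per set and are rough.

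In all, 19 gene lists were fixed before the data were examined, of which 6 are markers of other cell types. The lists for the neuromuscular junction, blood and nerve had no probe on the array. Lists with at least 4 probes were described by their median SD and by the mean pairwise correlation of their members. Both were placed among 10000 random lists of the same size matched on mean level in 5 bins, which describes these arrays and gives no p-value. Relations between lists used the mean of gene-standardised values per array, with exact two-sided permutation tests over all 5040 pairings for 7 arrays or 720 for 6. On simulated values for 7 arrays, the permutation test of r gave p under 0.05 in 8% of 200 unlinked sets. It did so in 98% of 200 sets linked with r near 0.95. Of 8 planned pairs of lists, 1 had 4 or more probes on both sides.

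The named genes follow a rule fixed beforehand. It takes Tnc, the 10 named probes with the highest mean signal, the 10 with the largest SD, the 5 with the smallest SD above the median level, probes past the variability test, and the brightest and most variable member of each list. Any other gene named in the text was chosen after its values were seen. Alternatives were quantile normalization, a filter on the dimmest probes (25th percentile of mean signal, 166 probes kept), a pseudocount of 0.05% (the 10th percentile of all values), a fit without trend and robustness, and leaving out each replicate. Median-centring, dropping the 2 probes outside the sum, the combination of leaving out replicate 3 with another scaling, and relations within the 2 parts of the arrays by 28S signal were added after seeing the data. Using the values as deposited, rescaling to a common sum and keeping all probes coincide with the main setting. The analysis used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The number of arrays and the rounding step limit the precision.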

Results

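Transcript signals were measured on a 223-probe array in soleus muscle of 7 tenascin-C-deficient mice. The series holds no second group, so the comparisons are between the 7 mice and between groups of genes, and no effect of the missing gene can be estimated. The array carries probes for contractile and metabolic genes, matrix and adhesion genes, growth factors, vessel growth, myogenic factors and the cell cycle. Of the 223 probes, 38 were clearly above the floor on each of the 6 arrays other than replicate 3, and 9 were so on all 7. No array showed a clear signal for 127 probes. The number of probes clearly above the floor per array ran from 29 in replicate 3 to 70 in replicate 6. The median probe carried 0.07% of the array sum in replicates 1 and 2, 0.18% in replicate 3, and 0.13%, 0.11%, 0.10% and 0.08% in replicates 4 to 7.

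The first question was whether the transcript of the targeted gene was seen. The Tnc probe carried 0.133% ± 0.039 of the array sum (SD, n = 7), from 0.08% in replicate 1 to 0.18% in replicate 4. That was 0.94 to 1.5 times the median probe of the same array, and it was clearly above the floor on none of the 7 arrays. Tnxb, which encodes a related tenascin, carried 0.153% ± 0.021 (SD, n = 7) and was clearly above the floor on 2 arrays. Without an array from a mouse with the intact gene, the Tnc signal cannot be called lower than normal. Whether the probe lies inside the deleted part of the gene is not given in the sources used here.

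The next comparison was between the mice. Among probes inside the array sum, which leaves out 28S rRNA and 1 unnamed bright probe, the brightest in 6 of the 7 muscles belonged to slow-fibre, glycolytic and mitochondrial genes, and replicate 3 differed from these 6 in nearly all of them. Myh7, the slow myosin heavy chain, carried 9.71% ± 1.66 of the sum and Mb, which encodes myoglobin, 7.96% ± 0.78 (SD, n = 6), against 0.35% and 0.32% in replicate 3. The glycolytic genes Aldoa and Gapdh carried 10.8% ± 1.7 and 10.4% ± 3.4 against 0.65% and 0.66%. Cox6a2, a muscle subunit of cytochrome c oxidase, carried 6.43% ± 1.94 against 0.51%. Over all 7 arrays the means were 8.37% ± 3.85 for Myh7, 6.87% ± 2.97 for Mb, 9.36% ± 4.15 for Aldoa, 8.97% ± 4.79 for Gapdh and 5.58% ± 2.85 for Cox6a2 (SD, n = 7).

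**Figure D1:**
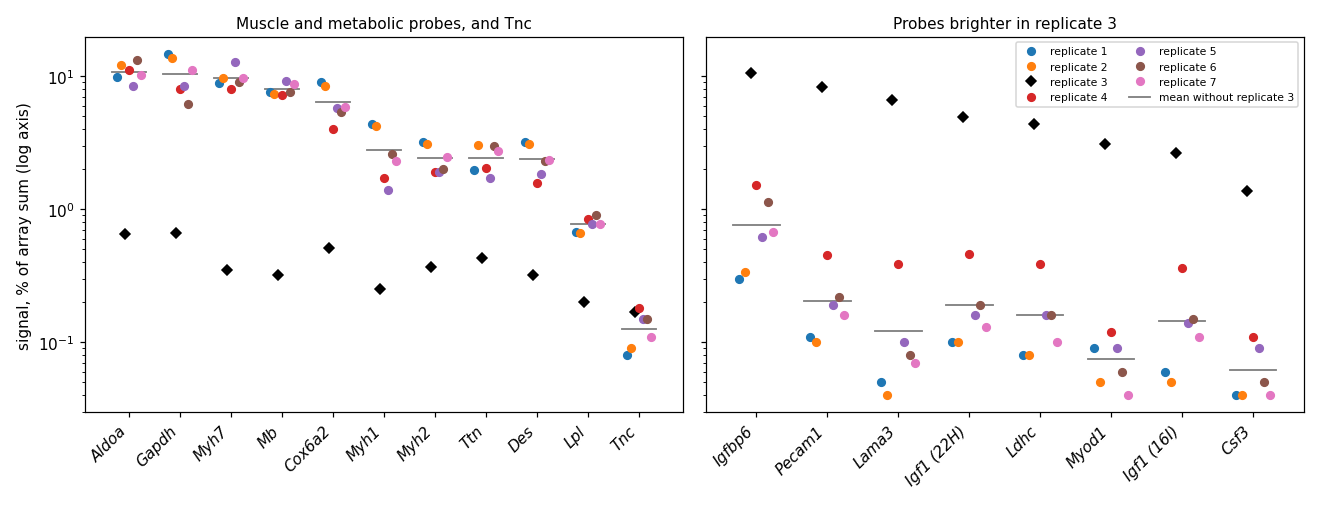
Signal of each named probe on each array, in percent of the array sum on a log axis; coloured circles are replicates 1, 2 and 4 to 7, the black diamond is replicate 3, and the grey line is the mean without replicate 3. Myh7 reads 0.35% in replicate 3 and 7.98% to 12.8% on the other arrays, while Igfbp6 reads 10.5% in replicate 3 and 0.30% to 1.51% elsewhere.

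Other probes were brighter in replicate 3. Igfbp6, which encodes an IGF-binding protein, carried 10.5% there and 0.765% ± 0.473 on the other arrays (SD, n = 6). Pecam1, an endothelial adhesion molecule, carried 8.36% against 0.205% ± 0.128, and Lama3, a laminin chain, 6.57% against 0.122% ± 0.133. The 2 probes for Igf1 carried 4.93% and 2.66% against 0.190% ± 0.137 and 0.145% ± 0.113. Ldhc, the testis-type lactate dehydrogenase, carried 4.38% against 0.162% ± 0.118, the myogenic factor Myod1 carried 3.11% against 0.075% ± 0.030, and Csf3, which encodes a colony-stimulating factor, carried 1.36% against 0.062% ± 0.031. Across all probes, replicate 3 was below every other array for 32 and above every other array for 157. The array medians above show that many of the latter lie near a higher floor. With 1 array there is no replicate check on this profile.

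Correlations across probes set replicate 3 apart as well. Between log2 signals of the other 6 arrays, Pearson's r ran from 0.876 to 0.992 with a median of 0.953 (15 pairs), and Spearman's rho had a median of 0.893. The 6 pairs with replicate 3 had r between 0.248 and 0.412 and a median rho of 0.356. Probes are not independent replicates, so these values only describe the arrays. The highest r, 0.992, was between replicates 1 and 2, whose titles carry different codes, C16 and C15. The SD of their log2 differences was 0.24, and their signals agreed within 1 rounding step for 153 of the 223 probes. With 127 probes clearly above the floor on no array, such agreement is easily reached, and it was not counted for other pairs. Sampling noise cannot be derived from intensities, and replicates 1 and 2 were counted as separate samples. If they are not independent, the sample sizes and exact p-values given here overstate the evidence.

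**Figure D2:**
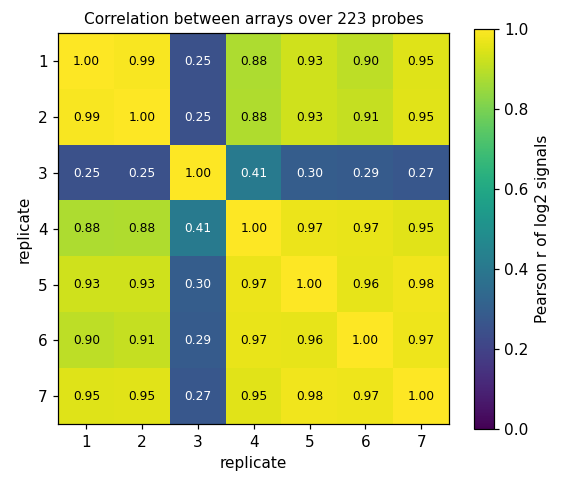
Pearson correlation of log2 signals over 223 probes for each pair of the 7 arrays, replicates on both axes. Replicate 3 lies between 0.25 and 0.41 with the others, and all other pairs lie at 0.88 or above.

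Most contractile and many metabolic genes were well measured. Of the contractile lists, both slow probes and all 3 fast probes were clearly above the floor on the 6 arrays other than replicate 3. On these 6 arrays the fast heavy chains Myh2 and Myh1 carried 2.43% ± 0.59 and 2.78% ± 1.26, and the giant sarcomeric protein gene Ttn 2.42% ± 0.57 (SD, n = 6). Between these 6 mice Myh7 and Mb varied little, with an SD of 0.23 and 0.14 on the log2 scale, while Myh1 had an SD of 0.67. Myh1 read 4.41% and 4.20% in replicates 1 and 2 and 1.40% to 2.62% in replicates 4 to 7. Gapdh, Cox6a2, Myh2, Myh4 and Des were also higher in replicates 1 and 2 than in each of replicates 4 to 7, whereas Myh7 and Mb were not. The 28S rRNA signal splits these arrays in the same way, so the spread of Myh1 cannot be told apart from that split. The difference in spread was not tested. All 3 respiratory chain probes and both probes of the citric acid cycle list were clearly above the floor on the same arrays. Pdha1, a subunit of pyruvate dehydrogenase, carried 0.830% ± 0.148. In fatty acid handling 5 of 9 probes were so, among them Lpl, lipoprotein lipase, at 0.773% ± 0.096. Cpt1b, the muscle enzyme for fatty acid entry into mitochondria, carried 0.218% ± 0.026. In glucose and glycogen metabolism 6 of 10 probes were so. Of the 4 metabolic regulators only Ucp3, an uncoupling protein, was so, at 0.265% ± 0.060, while Tfam, a mitochondrial transcription factor, stayed near the floor at 0.073% ± 0.029.

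Most regulatory and matrix genes lay near the floor. Among 19 matrix and adhesion probes, 2 were clearly above it on all 6 arrays, namely Des, the muscle intermediate filament gene, at 2.39% ± 0.65 and the integrin gene Itgb1 at 0.383% ± 0.104 (SD, n = 6), and 12 were so on none. Of 15 myogenic and cell cycle probes, 1 was so on all 6, Mef2c at 0.637% ± 0.128, and 10 on none. Myf6, the myogenic factor of mature fibres, carried 0.168% ± 0.016. Of 16 growth factor probes 2 were so on all 6, Igfbp6 and Igf2, and 9 on none. None of the 15 vessel growth and hypoxia probes was so on all 6. Both stress and protein turnover probes stayed near the floor, with Capn3, a muscle calpain, at 0.082% ± 0.022. Markers of other cell types were few. The adipocyte marker Fabp4 carried 0.463% ± 0.114 on these 6 arrays, and endothelium can express it too. The leukocyte marker Il1b carried 0.063% ± 0.023, and the fibroblast-associated Fn1 0.123% ± 0.015 and 0.055% ± 0.018 on its 2 probes.

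Lama3, Pecam1 and Myod1 differed widely between replicate 3 and the other mice, and 28S rRNA (Rn28s1) also among the others. The signals of Myf6 and the receptor gene Igf2r, not clearly above the floor on every array, differed little. This spread was then tested against that of all probes at a like level. In limma's variance test over all 7 arrays, 0 of 223 probes were more variable than the trend after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 17. The trend was fitted to the same 7 arrays and so includes the deviation of replicate 3. Its SD was 1.73 for Myh7 (own SD 1.82) and 1.65 for Mb (own SD 1.75), against 0.46 and 0.44 without replicate 3. A drop in replicate 3 that bright probes share is therefore part of the trend, and this test could not call it. An adjustment over each list alone was not planned and was not corrected for the number of lists. With it, limma called both Igf1 probes among the 16 growth factor probes (adjusted p = 0.044). It also called Pecam1 among the 6 endothelial markers (adjusted p = 0.027), and none in the other 6 lists of at least 4 probes. The vessel list is among these 6 and also holds Pecam1, which did not pass over its 15 probes (limma adjusted p = 0.068). Igf1 and Pecam1 were both brighter in replicate 3. Without it their limma adjusted p over all probes was 0.21 and 0.38 for Igf1 and 0.46 for Pecam1. Among named probes the largest SDs were those of Lama3 (2.58 on the log2 scale, limma adjusted p = 0.244), Rn28s1 (2.51), Pecam1 (2.21) and Myod1 (2.14). Without replicate 3 they were 1.16, 1.63, 0.79 and 0.60. Among named probes above the median level the smallest SDs were those of Myf6 (0.13), Igf2r (0.17), Cpt1b (0.17), Igfbp5 (0.19) and Timp3 (0.20). In replicate 3 all of them read 0.16% to 0.19%, near its floor of 0.15%. In the same order they were clearly above the floor on 4, 3, 4, 1 and 2 of the 7 arrays. Their low SD thus includes background readings and does not show steady transcript levels. Without replicate 3, limma called 5 probes. They were Igf2, an embryonic growth factor (SD 1.68, adjusted p = 0.031), Il6st, the shared receptor subunit of the IL-6 family (1.54, adjusted p = 0.036), Ang, angiogenin (1.52, adjusted p = 0.036), Ccna1, cyclin A1 (1.45, adjusted p = 0.036) and 1 unnamed probe (2.46, adjusted p = 0.0031). No probe was called when replicate 3 was left out and the arrays were median-centred or quantile normalized, with 17 and 10 at an unadjusted p under 0.05. These 5 probes were dimmer in replicates 1 and 2 than in replicates 4 to 7. Igf2 carried 0.17% in both of the former and 0.70% to 2.42% in the latter. The 28S rRNA probe followed the same order, with 3.48% and 3.79% against 24.1% to 49.7%.

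**Figure D3:**
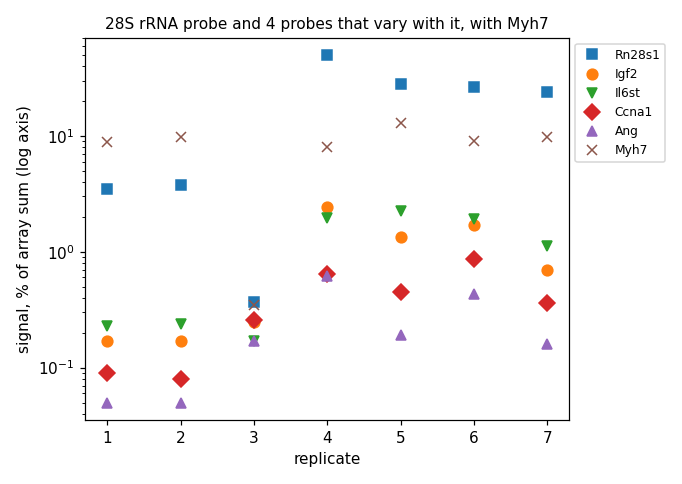
Signal of the 28S rRNA probe (Rn28s1), of Igf2, Il6st, Ccna1 and Ang, and of Myh7 on each of the 7 arrays, in percent of the array sum on a log axis; each point is 1 array. The 28S probe reads 3.48% and 3.79% in replicates 1 and 2 and 24.1% to 49.7% in replicates 4 to 7, and Igf2, Il6st, Ccna1 and Ang are lower in replicates 1 and 2 as well, whereas Myh7 is not.

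The probes for fatty acid handling and for matrix and adhesion had a low spread for their level on the deposited scale. The median SD of the 9 fatty acid probes was 0.54 (log2), at the 3.7th percentile of random lists, whose median was 0.73. Without replicate 3 it was 0.31, at the 6.0th percentile. The 19 matrix probes had a median SD of 0.52, at the 2.3th percentile, and 0.34 at the 5.1th without replicate 3. Of these, 12 were clearly above the floor on none of the 6 arrays other than replicate 3. The low spread of the matrix list thus includes background readings and does not show steady transcript levels. After median-centring the fatty acid list had 0.69, at the 20.6th percentile, and the matrix list 0.34, at the 17.6th. With quantile normalization the values were 0.50, at the 2.1th, and 0.29, at the 10.7th. The glucose list (0.75), the myogenic list (0.68), the growth factor list (0.72), the vessel list (0.61), the endothelial markers (0.66) and the metabolic regulators (0.58) lay between the 22nd and 77th percentiles on the deposited scale. Without replicate 3 these were 0.41, 0.46, 0.42, 0.34, 0.49 and 0.37, at the 66.2th, 74.0th, 39.5th, 13.5th, 80.0th and 31.8th percentiles. After median-centring other lists had the lower spread for their level, namely the metabolic regulators (0.22, at the 5.2th percentile), the endothelial markers (0.32, at the 6.9th), the glucose list (0.60, at the 9.2th) and the vessel list (0.31, at the 9.6th). In the same order, 3 of 4, 3 of 6, 3 of 10 and 9 of 15 probes were clearly above the floor on none of the 6 arrays other than replicate 3.

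Signals of the members of some lists moved together between arrays. The mean pairwise r was 0.75 for growth factors, at the 99.8th percentile of random lists, 0.66 for vessel growth, at the 98.9th, and 0.84 for the 6 endothelial markers, at the 99.6th. All 6 endothelial markers also belong to the vessel list. The random lists matched to these 3 had a median of 0.33, 0.33 and 0.079. Without replicate 3 it was 0.47, 0.47 and 0.54, so the high percentiles over 7 arrays depend on that array, which enters the matching level. In the same order, 9 of 16, 9 of 15 and 3 of 6 probes were clearly above the floor on none of the other 6 arrays. Their shared movement thus includes background readings. Without replicate 3 the 3 values were 0.63, 0.65 and 0.77, at the 90.0th, 89.8th and 89.7th percentiles, and with median-centred arrays they were 0.11, 0.071 and -0.0071, at the 95.1th, 87.8th and 71.6th percentiles of random lists, which then centre near 0. The fatty acid probes had a mean r of 0.29, at the 98.3th percentile, and 0.36 without replicate 3, at the 98.2th. It was 0.63 after median-centring and 0.75 with quantile normalization, at the 99.9th and 99.8th percentiles. The glucose list had a mean r of -0.037, the matrix list 0.38, the myogenic list 0.40 and the metabolic regulators 0.74. These lay at the 20.6th, 39.6th, 20.2th and 84.7th percentiles. Without replicate 3 they were 0.064, 0.23, 0.39 and 0.78, at the 49.2th, 2.3th, 9.5th and 91.8th. After median-centring they were 0.12, 0.13, 0.0076 and -0.18, at the 75.2th, 97.8th, 22.2th and 17.2th, and with quantile normalization the matrix list had 0.21, at the 99.5th.

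The 1 relation between lists that could be tested as planned was that of matrix and adhesion with myogenic factors and the cell cycle. The 2 list scores rose together across the 7 mice, with r = 0.96 (exact permutation p = 0.0038) and rho = 0.86 (exact permutation p = 0.024). Without replicates 1 and 3, the 2 farthest from the median matrix score, r was 0.91. Without replicate 3 alone r was 0.92 (exact permutation p = 0.031, n = 6) and rho 0.71 (exact permutation p = 0.14). After median-centring of the arrays r was 0.37 (exact permutation p = 0.41), so the relation no longer passed. Adjusted over all 8 planned pairs, 7 of them below the planned minimum of 4 probes, p was 0.010 over 7 arrays and 0.093 without replicate 3. Most members of both lists lay near the floor. The 6 remaining arrays also split by the 28S signal into 2 and 4. As deviations from the mean of each part, the 2 scores had r = 0.86, which did not pass (exact permutation p = 0.083 over 48 pairings within the parts, the smallest possible being 0.021).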

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

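All tests of explanations in this part were chosen after the results were seen. Of 36 values examined for 1 array far from the other 6 by Dixon's test (gap to the nearest array over the whole range), 18 stood out, each time because of replicate 3. Chance alone gives about 1 in 20, but that rate does not apply to probes chosen for a large SD or mean on these arrays, as many of these were. Replicate 3 was lowest for Mb (0.929), Myh7 (0.868), Aldoa (0.853), Lpl (0.788), Myh2 (0.763), Gapdh (0.723), Cox6a2 (0.717), Ttn (0.713), Des (0.694), Pdha1 (0.615) and Myh1 (0.600), and for the median correlation with the other arrays (0.941). It was highest for Myod1 (0.748), Csf3 (0.713), Pecam1 (0.660), 1 of the 2 Igf1 probes (0.608), Capn3 (0.607) and Ldhc (0.604).

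The first pattern is the profile of replicate 3. Weak labelling over a uniform background is argued against, since after subtraction of each array's floor 36 probes of replicate 3 still exceeded 3 times the highest of the other arrays. The dimmest of these, such as Igf1r at 0.19%, lay near the floor of replicate 3 and carry little weight here, unlike Pecam1 (8.36%) or Lama3 (6.57%). RNA of another tissue, as the whole cause, was examined with 6 probes for genes used in most cells. Their floor-subtracted signal had a median of 0.0623 of the mean of the other arrays (0.061 for Cox5b and 0.066 for Rps29, but 0.58 for Cox4i1). The median met the condition set against this explanation, but for most of these probes it cannot decide the question. Gapdh, Pgk1, Cox5b and Cox4i1 are glycolytic or mitochondrial genes, a kind bright in the other 6 muscles, so RNA without muscle could lower them too. The 28S probe lies outside the sum and ran from 3.48% to 49.7% on those 6 arrays. Neither point covers Rps29, a ribosomal protein gene, but it is 1 probe on 1 array and does not settle the question. Endothelial cells are neither supported nor excluded, since of the 6 endothelial markers, which the vessel list holds too, 2 were clearly above the floor of replicate 3, Pecam1 (8.36%) and Cdh5 (0.60%), and Kdr, Tek and Nos3 read 0.16%, near its floor of 0.15%. A fault in priming, labelling or hybridisation of that array, alone or together with another RNA, stays open. So do RNA of another tissue alone and a difference between mice, for which the design gives no group.

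The second pattern is that many probes brighter in replicate 3 than elsewhere were also raised in replicate 4. Of the 36 probes, 20 were highest in replicate 4 among the other 6 arrays after floor subtraction, against 33 of the remaining 187. Not all of the 36 were clearly above the floor of replicate 3, and for the dimmest the excess in replicate 4 is a few rounding steps or less. If a single share of the replicate 3 signal had entered replicate 4, the best share would be 4.06%, but the scatter around it gave a chi-square of 2.67 per degree of freedom, between the bounds set for and against. Lama3 (4.4%) and Igf1 (5.8% and 8.1%) lay above Myod1 (1.1%). Carry-over and a shared fault of lesser degree cannot be told apart for these probes.

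The third pattern is the group of 12 probes, besides 28S, with an SD above 1 on the log2 scale among the 6 arrays without replicate 3, all lower in replicates 1 and 2 than in replicates 4 to 7. Of these, 11 correlated with the 28S rRNA probe at 0.8 or more, which is 66.0 percentage points more than among the other 210 probes, and the first principal component of all probes correlated with it at r = 0.932 (exact permutation p = 0.0042, n = 6). The 28S probe parts the same arrays as these probes, so both values restate that split and do not tell a signal that follows rRNA from any other difference between replicates 1 and 2 and replicates 4 to 7. Median-centring left 0.780 of the median SD, between the bounds set for and against the authors' scaling. All of these explanations stay open, and no biological explanation was tested.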

How the results depend on the processing

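Median-centring, the floor criterion and dropping the 2 probes outside the sum were chosen after the results were seen. Of 245 alternative values, 228 stayed on the same side of a test or within the spread of the reported value, which for a list is the wide SD over its members or pairs. Some of the 228 could not change. No list holds the 2 probes outside the sum, so dropping them leaves every list value as it was. With no value at or below 0, the count of measured probes stays at 223 when a replicate is left out. The 228 thus overstate how firm the results are. The 1 relation between lists tested as planned kept its direction. Relations added later are not among the 245, and some changed sign. Of the 17 others, 6 came from median-centring, 5 from quantile normalization and 3 from leaving out replicate 3. The mean pairwise r, which has no test, changed sign in 8 cases over 4 lists, namely glucose, metabolic regulators, myogenic factors and endothelial markers. The count of probes past the variability threshold ran from 0 to 5 when each replicate was left out, and 5 was reached only without replicate 3. The median SD of the fatty acid list ran from 0.31 to 0.59 and that of the metabolic regulators from 0.37 to 0.64, both lowest without replicate 3. The latter was also 0.24 with quantile normalization, 0.39 with the pseudocount and 0.22 after median-centring. Quantile normalization and median-centring brought the mean pairwise r within lists to -0.15 and -0.18 for the metabolic regulators, 0.036 and 0.11 for growth factors, 0.081 and 0.071 for vessel growth, and -0.017 and -0.0071 for endothelial markers. Median-centring brought the matrix and myogenic relation to r = 0.37, whereas quantile normalization left it at 0.86 (exact permutation p = 0.014, adjusted p = 0.055 over the 8 pairs). With quantile normalization and without replicate 3, r was 0.72 (exact permutation p = 0.090). The cause was not tested. The number of probes measured in all samples was 126 if values had to exceed the 10th percentile of all values, and 9 with the floor criterion, since both are stricter by construction. The Tnc level stayed between 0.125% and 0.142%, and the median correlation between arrays between 0.900 and 0.953, when each replicate was left out. Probes near the floor are recorded in steps of 0.01%, which limits what can be said of them. No paired analysis was possible because the series holds 1 group.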

Other observations

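The relations between lists with fewer than 4 probes, and all relations after median-centring, were tested only after the results were seen. Several genes outside the lists were also bright. On the 6 arrays without replicate 3, Car3, a carbonic anhydrase of slow muscle, carried 1.43% ± 0.55, Rps29, a ribosomal protein gene, 2.18% ± 0.54, and Cox8a, another cytochrome oxidase subunit, 0.453% ± 0.097 (SD, n = 6). Eno2, the neuronal-type enolase, carried 0.33% ± 0.090 and was clearly above the floor on all 6, as was Pole2, a DNA polymerase subunit, at 0.528% ± 0.155. Among list members and others that were brighter in replicate 3, the signal of Pole2 there was 1.28%, that of Itgb1 1.28% and that of the glucose transporter gene Slc2a4 2.22%. Of the matrix list, the metalloproteinase genes Mmp2 (0.105% ± 0.014) and Mmp9 (0.055% ± 0.018) were clearly above the floor on no array. Among 2-probe genes, the Igf1 probes were both raised in replicate 3, while both Fn1 probes read 0.16% there.

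The Car3 value of replicate 6, 2.2141%, is the only one of 1561 values with more than 4 decimals as deposited. The unnamed probe outside the array sum read 121%, 85.2%, 4.86%, 134%, 110%, 30.1% and 44.0% of the sum in replicates 1 to 7.

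All 8 planned pairs of lists were also examined with a minimum of 2 probes, a limit chosen after seeing the data. Over 7 arrays on the deposited scale the metabolic regulators fell as the respiratory chain rose (r = -0.80, exact permutation p = 0.0034, adjusted p = 0.010), and so did matrix and adhesion (r = -0.90, exact permutation p = 0.0012, adjusted p = 0.0095). Of the 4 regulators, Ppara, Tfam and Pparg were clearly above the floor on no array. Of the 19 matrix probes, 12 were so on none of the 6 arrays other than replicate 3. Both scores thus include background readings. Without replicate 3 the regulator score was highest in replicate 4 (1.24), which had the highest median (0.13%), and lowest in replicate 2 (-1.16, median 0.07%). Slow contractile and respiratory chain probes had r = 0.98 (exact permutation p = 0.036, adjusted p = 0.071, rho = 0.54), and without replicate 3 r = 0.32 (exact permutation p = 0.51, n = 6). It was 0.79 without replicates 3 and 5. The other 4 added pairs did not pass on the deposited scale. Without replicate 3 the 2 negative relations had r = -0.87 (exact permutation p = 0.021) and r = -0.83 (exact permutation p = 0.035), and no pair passed after adjustment over the 8 (lowest adjusted p = 0.093). With either rescaling the sign turned for matrix and adhesion with the respiratory chain. For the regulators it turned only after median-centring without replicate 3. Whether the constraint of a fixed sum caused the negative signs was not tested. After median-centring the regulators and the respiratory chain had r = -0.42 over 7 arrays (exact permutation p = 0.36) and 0.062 without replicate 3 (exact permutation p = 0.89). Matrix and adhesion with the respiratory chain turned to r = 0.68 (exact permutation p = 0.078) and 0.93 (exact permutation p = 0.0083, adjusted p = 0.033). With quantile normalization over 7 arrays the 2 pairs had r = -0.076 (exact permutation p = 0.86) and 0.54 (exact permutation p = 0.22). Without replicate 3 they had r = -0.65 (exact permutation p = 0.18) and 0.29 (exact permutation p = 0.59). Slow contractile and respiratory chain probes had r = 0.96 after median-centring (exact permutation p = 0.0012, adjusted p = 0.0056) and 0.94 without replicate 3 (exact permutation p = 0.0069, adjusted p = 0.033). With quantile normalization they had 0.92 (exact permutation p = 0.0040, adjusted p = 0.032) and 0.30 (exact permutation p = 0.70). The array medians (0.07% to 0.18%) lay near the floors (0.04% to 0.15%). Median-centring thus divides all bright probes of an array by the same near-background value. How much of the positive r after median-centring comes from this shared factor was not tested. Median-centring also brought respiratory chain with fatty acid handling to r = 0.98 (exact permutation p = 0.0014, adjusted p = 0.0056) and slow with fast contractile probes to 0.93 (exact permutation p = 0.0056, adjusted p = 0.015). Without replicate 3 these 2 had 0.84 and 0.76 and did not pass (adjusted exact permutation p = 0.089 and 0.11), whereas respiratory chain with glucose metabolism had 0.90 (exact permutation p = 0.017, adjusted p = 0.044). With quantile normalization no pair passed without replicate 3 (lowest adjusted exact permutation p = 0.18).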
